A study of Homo sapiens with 16 samples.

How the data were processed

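Chromatin immunoprecipitation with sequencing (ChIP-seq) had been carried out on 4 untreated human cell lines, each with antibodies against 3 histone modifications and with an input library, which made 16 samples. The 12 immunoprecipitated libraries each had a peak list, and the inputs entered through those lists. Each line and mark was represented by 1 library. No test between lines was therefore possible, no p-value is given, and every difference is a difference between libraries.

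Per the labels' protocols, HuT78 and K562 were grown in another medium than Jurkat and Raji, and the libraries were read as paired ends on a NextSeq 500. Cutadapt, Bowtie2, MACS2 and deepTools are named in the submitters' processing notes without versions, and those notes list both GRCh38 and hg19. Per the file headers, the lists are in hg19 and each library was compared with the input of its own line, with narrow peaks for H3K27ac and broad peaks for H3K27me3 and H3K9me3. The names of the deposited peaks carry a q cutoff of 0.05. The only value per peak in the deposited lists is an unnamed column taken here, from its values, as the authors' fold enrichment, a ratio of the immunoprecipitated library to its input. In the 3 long H3K27ac lists many of these values were whole multiples of a single step, within a tolerance of 2e-05, namely 11.8% of the HuT78 peaks, 29.3% of the Jurkat peaks and 26.3% of the K562 peaks, where an even spread of values would give about 0.012%. Fold was used to describe, rank and filter peaks within a list. Read totals per library were not given in the sources used here.

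Peaks on autosomes and the X chromosome were kept. In 11 of the lists the running peak number jumped once, between chromosome 9 and the X chromosome, by up to 464 numbers, and the Raji H3K27ac list had no jump. What those numbers stood for was not determined. Chromosome lengths, cytogenetic bands and Giemsa stain classes of hg19 came from the band table shipped with the R package circlize 0.4.16 under R 4.3.3. Everything else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are 1-based hg19 positions. The gene table at hand was made for another assembly, so no peak was assigned to a gene. The planned counts of marked promoters, shares of gene lists, gene body coverage and values at SATB1 itself were not made, and regions are named by position and band instead.

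A peak was counted as shared when at least 1 bp overlapped a peak of the other list, and as missing in the other line when that line had no peak of the mark within 5 kb. Overlap by chance was estimated by rotating a list 100 times along each chromosome within the 100-kb bins that held a peak of any library (28249 bins, 2824.9 Mb), and the lowest and highest of the rotations are given as a range. For acetylation missing in a second line, H3K27ac and the repressive mark of that line were rotated together and the missing peaks were picked anew in each rotation, so that chance carried the same selection. Percentages of peaks carry 95% Wilson intervals, which cover counting error only, and neighbouring peaks are not independent. Broad peaks closer than 10 kb were joined into domains. The counting of overlaps was tested on simulated lists of 20000 peaks, where 18067 of 18067 planted overlaps were recovered. A single pair of unrelated lists of short, randomly scattered peaks gave a ratio to chance of 1.02, with every bin open to placement. Clustered or broad peaks were not simulated. For the joint rotation, 20 rotations of the HuT78 H3K27ac list against fixed Jurkat lists gave a mean ratio of 0.993 (0.898 to 1.06). Chance was itself made by rotation, so such a ratio follows by construction. It checks the code and not whether this chance suits the data.

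What to name was fixed before the data were examined. For each mark it was to be the 10 highest-ranked genes with a HuT78 peak at the promoter and no peak of the other line within 5 kb of their starts. The other line was Jurkat or K562, and the 10 of each reverse comparison were to be named too. Since no peak was assigned to a gene, the 10 highest-ranked HuT78 peaks missing in the other line, and the reverse, replaced these genes. The 5 longest domains of each broad mark and line were fixed as well. The ranking was to use the q value of the peaks, which was not among the values used, and fold replaced it. The planned cutoff on q was likewise replaced by a fold of at least 4 for H3K27ac and at least 3 for the broad marks. These replacements, the thinning of lists by fold, the 5-kb version of sharing, and the comparisons by chromosome, Giemsa class and 100-kb bin and of acetylation missing in a second line, with its joint rotation, were chosen after seeing the data. Other alternatives were autosomes only, joined broad peaks, overlap over at least 0.5 of both peaks and overlap of 500 bp.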

Results

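Acetylation of histone H3 at lysine 27 (H3K27ac, a mark of active promoters and enhancers), trimethylation of the same residue (H3K27me3, the mark of Polycomb repression) and trimethylation of lysine 9 (H3K9me3, a mark of heterochromatin) were mapped by ChIP-seq in 4 untreated human lines. HuT78 derives from Sézary syndrome, a leukemic cutaneous T cell lymphoma, and is the line closest to the disease in the study's title. Jurkat is an acute T cell leukemia line, K562 a chronic myelogenous leukemia line and Raji a Burkitt's lymphoma line of B cells. Each line and mark had 1 library, so there was no replicate error against which a difference between lines could be set. Read depth was not known, and the lists differed widely in length.

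HuT78 had the least sequence under H3K27ac peaks of the 3 lines with long lists. Its 98216 H3K27ac peaks covered 47.7 Mb (1.57% of the autosomes and X chromosome), against 218328 peaks and 95.2 Mb (3.14%) in Jurkat and 207141 peaks and 90.9 Mb (2.99%) in K562. H3K27me3 peaks were similar in number, with 132225 in HuT78, 133239 in Jurkat and 134120 in K562, but covered 217.6 Mb, 188.0 Mb and 368.2 Mb. Neither the similar number nor the order of HuT78 and Jurkat held at a fold of at least 3, where 47756, 106051 and 61104 peaks covered 139.3 Mb, 170.9 Mb and 291.0 Mb. H3K9me3 peaks covered most in Jurkat, with 244.9 Mb in 108051 peaks, against 138.6 Mb in 132645 peaks in K562 and 62.8 Mb in 62265 peaks in HuT78, but with peaks joined over 10 kb they covered 403.9 Mb in Jurkat and 430.9 Mb in K562. Raji had 8646 H3K27me3 peaks over 4.56 Mb, 683 H3K9me3 peaks over 0.287 Mb and 44 H3K27ac peaks over 0.00922 Mb, and its H3K27ac list was left out of the comparisons between lines.

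Chromosome 19, which holds the large clusters of KRAB zinc finger genes, was the chromosome with most H3K9me3 in every line with long lists. H3K9me3 peaks covered 12.9% of it in HuT78, 23% in Jurkat and 13.7% in K562, against 2.07%, 8.07% and 4.57% of all chromosomes together. The X chromosome separated the lines more sharply, with 10.6% of it under H3K9me3 in Jurkat, 0.151% in HuT78 and 1.47% in K562. H3K27me3 was densest on chromosome 20 in HuT78, at 17.7%, and in Jurkat, at 11.9%, and on chromosome 17 in K562, at 21%. The X chromosome was the least covered by H3K27me3 in all 3 lines, at 0.810%, 0.310% and 3.64%. The number of copies of each chromosome was not measured and can move these values.

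**Figure D1:**
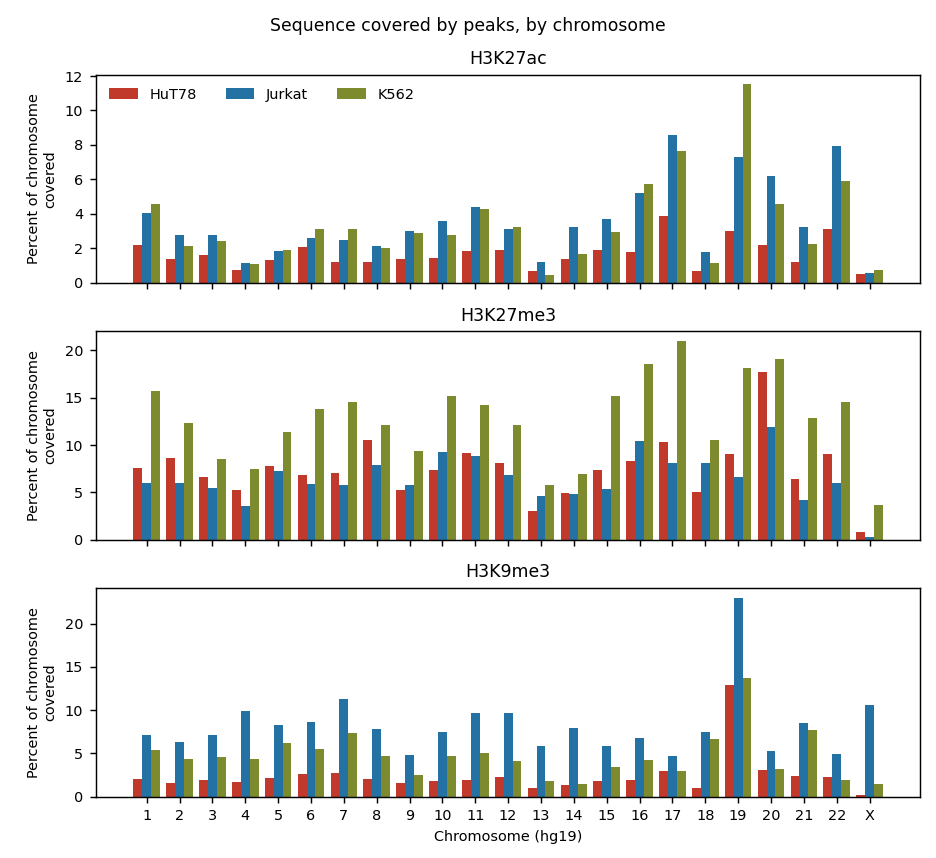
Percent of each chromosome (horizontal axis, hg19) covered by peaks of H3K27ac, H3K27me3 and H3K9me3 (vertical axes, percent) in HuT78, Jurkat and K562, with 1 library per bar. Chromosome 19 stands highest for H3K9me3 in each line, and the X chromosome carries 10.6% in Jurkat against 0.151% in HuT78.

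Acetylation followed the light, gene-rich Giemsa bands in all 3 lines. H3K27ac covered 2.32% of the unstained bands and 0.497% of the darkest bands in HuT78, 5.11% and 0.499% in Jurkat, and 4.80% and 0.501% in K562. H3K27me3 in K562 showed the same slope, with 17.8% of unstained and 2.08% of the darkest bands. H3K9me3 went separate ways. In HuT78 it covered 2.74% of unstained and 0.732% of the darkest bands, in Jurkat 7.44% and 8.92%, and in K562 3.86% and 5.78%.

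The longest H3K9me3 domains of HuT78 all lay on chromosome 19. The first reached over 1377 kb of 19p12 (21834365 to 23210977), and the others lay at 19q13.12 (36800153 to 37772318), 19q13.43 (56848369 to 57723987), 19q13.41 (52743336 to 53417387) and 19q13.41 to 19q13.42 (53428621 to 54033945). Jurkat H3K9me3 peaks covered 97.4%, 90.7%, 91.5%, 87.6% and 91.2% of these 5 domains, and K562 peaks 49.1%, 59.5%, 71.8%, 44.5% and 49.4%. Of the HuT78 domains of at least 100 kb, 26 of 78 lay on chromosome 19, against 22 of 305 in Jurkat and 30 of 565 in K562.

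Jurkat formed H3K9me3 domains of megabase size, and H3K9me3 peaks of the other lines covered far less of the longest. These domains were picked by their length in Jurkat. Over all chromosomes H3K9me3 covered 8.07% in Jurkat, 4.57% in K562 and 2.07% in HuT78. The longest spanned 2694 kb of 4q35.2 (187768774 to 190462992), where Jurkat peaks covered 81.3% of the sequence, K562 peaks 7.26% and HuT78 peaks 1.61%. At 7q11.22 (67093769 to 69025168) the values were 99.1%, 3.42% and 2.18%, and at 14q31.2 to 14q31.3 (84339343 to 86517104) they were 83.2%, 1.8% and 0.515%. The remaining 2 of the 5 longest lay at 5q23.2 (123503939 to 125566123) and Xq27.2 to Xq27.3 (140685392 to 142741123). At 5q23.2 the values were 66.5%, 8.14% and 1.08%, and the X domain had no HuT78 H3K9me3. K562 thus lay above its level over all chromosomes at 4q35.2 and 5q23.2, and HuT78 slightly above its own at 7q11.22. The other values given for K562 and HuT78 in these domains lay below those levels. Jurkat had 83 domains of at least 500 kb, K562 22 and HuT78 9. The longest K562 domains lay elsewhere again, at 13q31.3 (90438820 to 91943522), 18q11.2 to 18q12.1 (24253194 to 25375513), 3p26.1 (7411848 to 8455598), 21q22.2 (41496140 to 42432868) and 15q25.3 (86458506 to 87359598). K562 peaks covered 37.4% to 63.6% of these and HuT78 peaks at most 1.02%.

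For H3K27me3, the longest HuT78 domain spanned 1012 kb of 2q14.2 (121077456 to 122089259). HuT78 peaks covered 78.7% of it, K562 peaks 81.1% and Jurkat peaks 18.5%. The next lay at 12p13.33 (2129564 to 2809237), 14q32.13 (94818384 to 95386961), 1p33 (48077725 to 48580055) and 17q12 (32751537 to 33236040). The longest Jurkat domains were at 10p13 (13946208 to 14470246), 17q24.3 (69728013 to 70238467), 20q12 to 20q13.11 (41464501 to 41952383), 11q25 (133078541 to 133525760) and 7q36.3 (155588255 to 156017166). At 17q24.3, H3K27me3 covered 43.2% in Jurkat, 23.1% in HuT78 and 1.17% in K562, while K562 H3K9me3 covered 28.3%. At 11q25 these values were 58.8%, 11.5%, 0% and 23.6%. The K562 list began with 6p21.2 to 6p21.1 (40351313 to 41002924), 2q14.2 (121059611 to 121690330), 1p36.32 (2917695 to 3540798), 1p36.23 to 1p36.22 (8967394 to 9588519) and 16q12.1 (49447952 to 50055617). The domain at 1p36.23 to 1p36.22 was covered to 89.4% in K562, 2.17% in HuT78 and 3.92% in Jurkat.

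The lines were then compared by position, with HuT78 set against each of the others. Of the HuT78 H3K27ac peaks, 51.4% (Wilson interval 51.1 to 51.7) were shared with Jurkat, where chance gave 6.98% (range 6.23 to 8.01), and 44.6% (44.3 to 44.9) with K562, where chance gave 6.76% (6.02 to 7.45). In the other direction 22% of Jurkat and 20.6% of K562 peaks met a HuT78 peak. HuT78 H3K27me3 peaks were shared with Jurkat for 38.1% and with K562 for 35.0%, against 12.4% and 18.7% by chance. HuT78 H3K9me3 peaks were shared for 59.6% and 40.6%, against 12.3% and 9.94%. Over 100-kb bins, the Spearman correlation of covered length between HuT78 and Jurkat was 0.678 for H3K27ac, 0.546 for H3K27me3 and 0.460 for H3K9me3, and between HuT78 and K562 it was 0.662, 0.280 and 0.264. Bins are not independent replicates. These shares depend on list length and on the overlap required. The longer list of each pair was also thinned by fold to the covered length of the shorter. The shares with Jurkat and K562 were then 32.3% and 29.7% for H3K27ac, 43.3% and 18.4% for H3K27me3, and 17.7% and 22.2% for H3K9me3. For H3K27me3 this cut HuT78 to 89687 peaks against Jurkat but cut K562 to 31538, so these shares have unlike bases. The order for H3K9me3 turned, but this thinning left 6403 Jurkat and 39486 K562 peaks of H3K9me3. Thinned instead to the same number of peaks, the shares were 37.9% and 34.9% for H3K27me3 and 51.5% and 28.5% for H3K9me3. For overlap over 0.5 of both peaks the shares with Jurkat and K562 were 18.4% and 16.5% for H3K27ac, 9.73% and 7.22% for H3K27me3, and 10.1% and 13.3% for H3K9me3.

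Although short, the Raji lists of methylated peaks met those of the other lines more often than chance. Of the Raji H3K27me3 peaks 46.5% met a HuT78 peak, 43.1% a Jurkat peak and 58.0% a K562 peak, against 11.2%, 9.80% and 16.7% by chance. For the Raji H3K9me3 peaks the shares were 67.2%, 83.6% and 72.3%, against 3.68%, 10.1% and 7.78%. The longest Raji H3K27me3 domain lay at 6q15 (90602732 to 90881818). Raji peaks covered 44.6% of its 279 kb, K562 peaks 23.4%, HuT78 peaks 0.0674% and Jurkat peaks 0%. The 5 longest Raji H3K9me3 domains lay at 21p11.2, 16q11.2, 1p36.31, 8q11.1 and 8p11.1, all but 1p36.31 in centromeric or variable bands. H3K9me3 of each other line covered 100% of the first, 61.8% to 91.9% of the second and 7.26% to 100% of the rest. Whether peaks in such bands are particular to the mark was not tested.

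Strong acetylation set HuT78 apart from Jurkat at single loci. The 10 HuT78 H3K27ac peaks of highest fold with no Jurkat peak within 5 kb had folds of 12.4 to 15.9. They were led by 3q25.31 (156533263 to 156534728, fold 15.9), 9q34.3 (140042500 to 140044776, fold 14.4) and 1q21.2 (147735294 to 147735780, fold 14.3), and included an 11216-bp peak at 1q31.2 (192514484 to 192525699, fold 13.2). Jurkat carried H3K27me3 within 5 kb of 6 of the 10. In reverse, the 10 Jurkat peaks missing in HuT78 had folds of 14.8 to 18.2, and HuT78 carried H3K27me3 near 7 of them. The strongest was a 14275-bp peak at 20q13.31 (56403510 to 56417784, fold 18.2), with 19265 bp of HuT78 H3K27me3 within 5 kb. It was followed by 16q12.2 (54082240 to 54088673, fold 18.1) and 15q11.2 (23810786 to 23811351, fold 17.2).

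The seventh of these Jurkat peaks lay at 3p24.3 (18016397 to 18024703, fold 15.3), the band to which SATB1, the chromatin organizer named in the study's title, is assigned. Neither HuT78 nor K562 had H3K27ac within 5 kb, and HuT78 had no H3K27me3 or H3K9me3 there, while K562 had 946 bp of H3K27me3. Which gene the peak belongs to was not determined. Over the whole band H3K27ac covered 1.29% in HuT78, 2.43% in Jurkat and 0.668% in K562. H3K27me3 covered 4.92%, 1.74% and 5.64%, and H3K9me3 covered 1.08%, 7.34% and 12.7%. The band is 7.5 Mb long, so these values do not describe SATB1 itself.

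Against K562, the strongest HuT78 H3K27ac peaks lay at 1q21.3 (153313651 to 153320684, fold 17.3), 14q32.12 (92979386 to 92985076, fold 15.6) and 5q11.1 (49962863 to 49965001, fold 14.4). Jurkat was acetylated within 5 kb of these 3, and K562 H3K27me3 lay near 9 of the 10 that were ranked. The K562 peaks missing in HuT78 were led by 5q31.1 (134368006 to 134369925, fold 17.9), with 11287 bp of HuT78 H3K27me3 within 5 kb, 4p16.3 (1037079 to 1039735, fold 16.2) and 2p23.3 (24231996 to 24234297, fold 16.0). HuT78 H3K27me3 lay near 8 of the 10, and K562's own H3K27me3 near 4, among them the peak at 4p16.3 with 3736 bp. In the other 3 comparisons of H3K27ac the line's own H3K27me3 lay near 0 of the 10. No chance value was computed for these counts of 10.

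The peaks of the broad marks that fold ranked highest varied in length. Among the 10 HuT78 H3K27me3 peaks missing in Jurkat, 4 were shorter than 1 kb, where the median of the whole list was 769 bp, and the longest was 6812 bp at 15q26.1 (89978439 to 89985250, fold 4.49). Of the Jurkat peaks missing in HuT78, 2 were shorter than 1 kb (median of the list 745 bp), and they included 15126 bp at 1q31.3 (197876475 to 197891600, fold 5.05). For H3K27me3 of K562 missing in HuT78, 9 of the 10 were shorter than 1 kb (median of the list 1086 bp), and for HuT78 missing in K562, 5. The 10 HuT78 H3K9me3 peaks missing in Jurkat ran from 152 to 4528 bp, with 7 shorter than 1 kb (median of the list 627 bp). Those missing in K562 ran from 151 to 1091 bp, with 9 shorter than 1 kb. The H3K9me3 peaks of Jurkat missing in HuT78 included a single peak of 239909 bp at 7p22.2 (4016681 to 4256589, fold 6.45) with a neighbour of 45800 bp (4257293 to 4303092, fold 6.65). The K562 ones included 3 peaks at 1p36.32, the first at 2614705 to 2624818 with a fold of 7.43.

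In the 3 lines with long lists, H3K27ac peaks overlapped the repressive marks less often than by chance. In HuT78, 0.554% of H3K27ac peaks (0.509 to 0.602) lay in H3K27me3, where chance gave 10.6%. In Jurkat the share was 2.0% (1.94 to 2.06) against 9.38%, and in K562 6.32% (6.22 to 6.43) against 16.8%. For H3K9me3 the shares were 0.302%, 2.51% and 1.71%, against 3.70%, 10.2% and 7.47%. Over 100-kb bins the relation varied. The Spearman correlation of H3K27ac with H3K27me3 was -0.345 in HuT78, -0.219 in Jurkat and 0.228 in K562, and with H3K9me3 it was 0.175, -0.113 and -0.179. H3K27me3 and H3K9me3 shared 8.47 Mb in HuT78, 1.64 times the chance length (range 1.41 to 1.93), 10.0 Mb in Jurkat, 0.638 times (0.580 to 0.708), and 12.7 Mb in K562, 0.661 times (0.605 to 0.732). With shifts kept within 1 Mb the K562 ratio was 0.948 (0.882 to 1.05), which was not below chance. The short Raji lists shared 0.00593 Mb, with 25 H3K27me3 peaks met, which was 12.9 times chance and at least 3.71 times every rotation. Counted by peaks, Jurkat also differed by direction: 13.4% of its H3K9me3 peaks met H3K27me3, 1.08 times chance (1.01 to 1.12), and 10.5% of its H3K27me3 peaks met H3K9me3, 0.848 times.

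**Figure D2:**
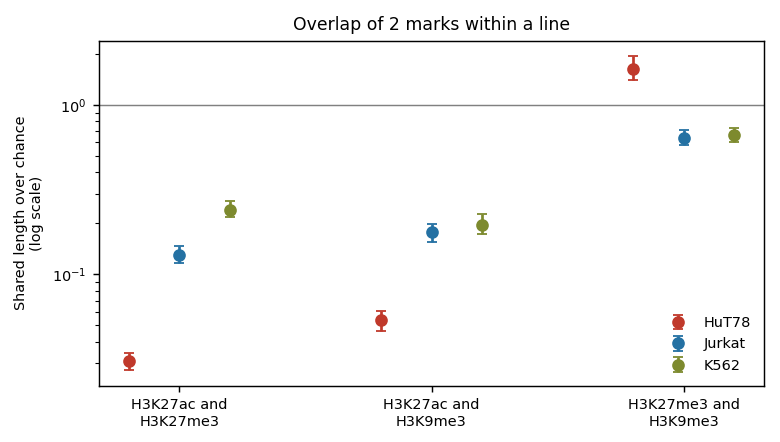
Length shared by 2 marks within a line over the length shared by chance (vertical axis, log scale) for the 3 pairs of marks (horizontal axis); points are libraries of HuT78, Jurkat and K562, and bars run over 100 rotations. H3K27me3 and H3K9me3 lie at 1.64 in HuT78 and at 0.638 and 0.661 in Jurkat and K562.

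Acetylation that was missing in a second line was set against that line's H3K27me3 in 6 ordered pairs of lines. A missing peak lies away from the second line's acetylation by selection, so chance was taken from rotations of both marks of the second line together, with the missing peaks picked anew. The share exceeded chance in 3 pairs and lay within its range in the other 3. These rotations ran along whole chromosomes and did not keep regional differences, and shifts within 1 Mb were not run here. Over 100-kb bins, H3K27ac of the first line and H3K27me3 of the second correlated at 0.440, 0.237 and -0.0749 for the 3 in excess. In the other 3 the correlations were -0.248, -0.154 and -0.191 (Spearman, pairs in the order below). An excess at the missing peaks themselves therefore cannot be told from one over whole regions. Of the 78579 Jurkat H3K27ac peaks with none in K562 within 5 kb, 60.1% (59.8 to 60.5) lay in K562 H3K27me3, against 18.6% by chance (range 16.0 to 21.2). For HuT78 peaks missing in K562 the share was 39.8% (39.3 to 40.4), against 18.2% (16.4 to 20.2). Jurkat peaks missing in HuT78 lay in HuT78 H3K27me3 for 19.2% (18.9 to 19.4), against 12.6% (11.3 to 13.9). There was no excess for HuT78 peaks missing in Jurkat, at 10.5% against 11.1%, for K562 peaks missing in HuT78, at 11.0% against 12.5%, or for K562 peaks missing in Jurkat, at 10.8% against 11.4%. With a fold of at least 4 in H3K27ac these 3 fell below the range of chance, to 0.847, 0.782 and 0.817 times its mean, while the first 3 stayed above it.

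**Figure D3:**
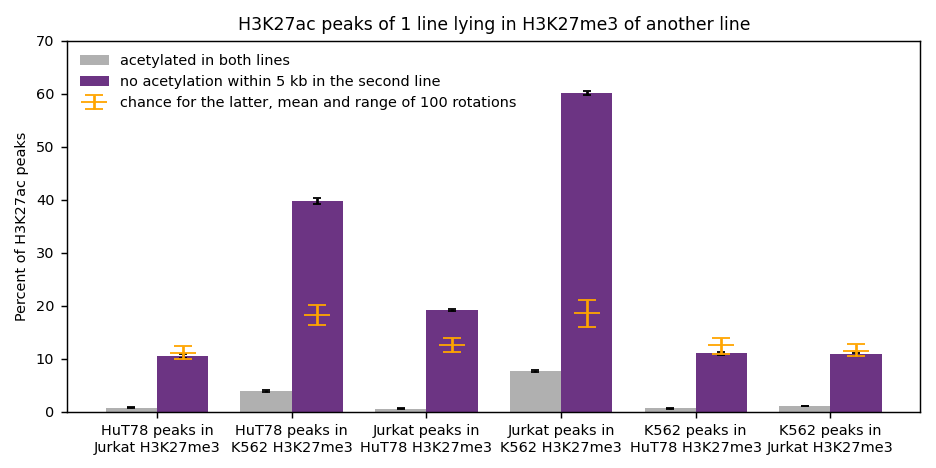
Percent of H3K27ac peaks of the first line lying in H3K27me3 of the second line (vertical axis) for 6 ordered pairs of lines (horizontal axis), for peaks acetylated in both lines and for peaks with no acetylation within 5 kb in the second; black bars are 95% Wilson intervals and orange bars the mean and range of 100 rotations for the latter peaks. Jurkat peaks missing in K562 reach 60.1%, against 18.6% by chance, and peaks acetylated in both lines are low by selection.

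H3K9me3 of the second line lay at fewer of these peaks. Its share was above the range of chance in 1 pair and below it in 5. The mark met 4.74% of the Jurkat peaks missing in HuT78, against 4.14% by chance (range 3.68 to 4.68). It met 3.32% of the HuT78 peaks missing in Jurkat, against 12.1%. For HuT78 peaks missing in K562 the share was 4.64%, against 8.52%, and for Jurkat peaks missing in K562 5.82%, against 8.38%. K562 peaks missing in HuT78 gave 3.21%, against 4.50%, and those missing in Jurkat 4.69%, against 12.7%. These rotations did not keep regional differences either. Over 100-kb bins, H3K27ac of the first line and H3K9me3 of the second gave Spearman correlations of 0.248, -0.199, -0.170, -0.177, 0.168 and -0.187. These follow the order of pairs given here. The shares at missing peaks thus cannot be told from placement over whole regions.

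The Raji H3K27ac list had its own geography. Of its 44 peaks, 22 lay in 424 kb of chromosome 9 (133642979 to 134066735, 9q34.12 to 9q34.13) and 21 in 1655 kb of chromosome 22 (21910138 to 23565525, 22q11.21 to 22q11.23). The remaining peak lay at 17q21.31 (41400618 to 41401095). In K562, H3K27ac peaks of the same stretches had a median fold of 2.35 on chromosome 9 and 2.70 on chromosome 22, against 3.86 over the genome. The K562 H3K27me3 peaks of these stretches had medians of 4.87 (7 peaks) and 2.48, against 2.96, and the H3K9me3 peaks 2.06 and 2.34, against 3.09.

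**Figure D4:**
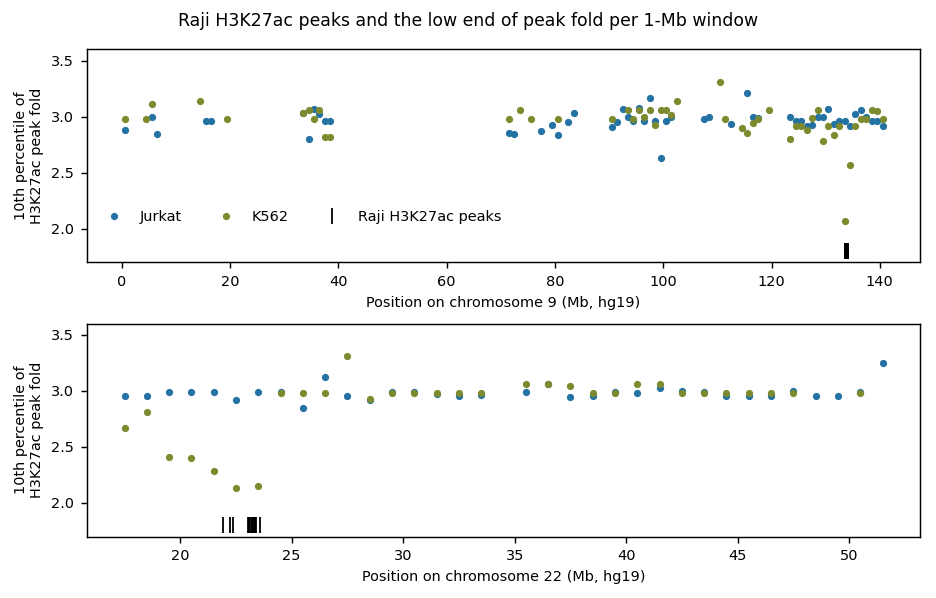
Raji H3K27ac peaks (ticks) on chromosomes 9 and 22 (horizontal axes, Mb, hg19) with the 10th percentile of H3K27ac peak fold per 1-Mb window (vertical axes) in Jurkat and K562, for windows with more than 30 peaks. K562 falls to 2.07 on chromosome 9, with 2.57 in the next window, and to 2.13 on chromosome 22, in windows that hold Raji peaks.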

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

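The K562 background and the overlap of the Raji peaks were tested after the result was seen.

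The Raji H3K27ac list was used in no comparison, yet 43 of its 44 peaks lay in the 2 stretches of 9q34 and 22q11. If they marked acetylation at sites that other lines acetylate too, they should meet such peaks more often than chance. They met 9, where rotation within the stretches gave 14 (range 6 to 25), a ratio of 0.645, while HuT78 and Jurkat peaks of the same stretches, treated alike, gave 2.19 and 1.85, each beyond every rotation. K562 DNA in the Raji library may be a source, since these bands are joined by the Philadelphia translocation that K562 carries, and extra DNA copies would lower the fold of K562 peaks there, although the 7 K562 H3K27me3 peaks on chromosome 9 had a higher median fold, 4.87 against 2.96. Of the 1-Mb windows holding Raji peaks, 4 had the lowest 10th percentiles of fold among 1284 windows of the K562 H3K27ac list. In Jurkat the lowest rank of such windows was 232. The K562 window from 134000001 on chromosome 9, with 9 Raji peaks, ranked 13. This lies between the limits of 10 and 50 set for the test, so K562 DNA stays open. The stretch ends at 134066735, so most of that window lies outside it and its rank depends on where the window border fell. Low coverage of the Raji input and acetylation at sites of Raji alone stay open too: the Raji H3K27me3 list held only 5 peaks in the stretches, 0.786 times its genome-wide density with an interval of 0.255 to 1.83 (3 on chromosome 9, 7.08 per Mb against 3.06 over the genome, and 2 on chromosome 22, 1.21 per Mb), and the latter was not tested.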

How the results depend on the processing

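Cutoffs and thinning by fold, the 5-kb version of sharing, the local shifts and every alternative for acetylation missing in the second line were chosen after seeing the data. Of 154 alternative values 74 stayed within the limit (1.5 times for counts, the interval or range otherwise), and 80 moved; most are counts or lengths, which cannot change sign. For the moves, beyond what fewer peaks or a longer required overlap give by construction, the cause was not tested. Restricting the lists to autosomes moved none of 36 values beyond the limit, but the ratio for K562 peaks missing in HuT78 went from within the range of chance to below it (0.872, range 0.771 to 0.993). Alternatives on q, on promoter windows, on gene lists, on gene bodies and on SATB1 were not run. No paired analysis was possible because each line and mark has 1 library. Read depth is not known, so a missing peak is not evidence that the mark is absent.

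With the stricter fold the H3K27ac lists held 53817 (HuT78), 94707 (Jurkat) and 85835 (K562) peaks, the H3K27me3 lists 47756, 106051 and 61104, and the H3K9me3 lists 40650, 52488 and 83600. Joined over 10 kb there were 26674, 30884 and 20815 H3K27me3 domains and 29535, 45132 and 42560 H3K9me3 domains in HuT78, Jurkat and K562. The order of covered length turned between HuT78 and Jurkat for H3K27me3 with the stricter fold (139.3 Mb and 170.9 Mb), and between Jurkat and K562 for joined H3K9me3 (403.9 Mb and 430.9 Mb).

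HuT78 peaks shared with Jurkat and K562 numbered, for overlap over 0.5 of both peaks, 18039 and 16171 (H3K27ac), 12866 and 9545 (H3K27me3), and 6263 and 8290 (H3K9me3). With the stricter fold they numbered 25792 and 22645, 22090 and 17877, and 22037 and 15994. With lists of the same length by fold they numbered 31748 and 29190 for H3K27ac, 24289 for H3K27me3 with K562, and 11009 and 13849 for H3K9me3. Within 5 kb they numbered 78270 and 67332 for H3K27ac, 83589 for H3K27me3 with Jurkat and 38926 for H3K9me3 with K562. HuT78 H3K9me3 peaks were shared more often with Jurkat than with K562 except for overlap over 0.5 of both peaks and for the same length. The latter left 6403 Jurkat and 39486 K562 peaks.

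With an overlap of 500 bp, H3K27ac peaks in H3K27me3 numbered 35, 131 and 873 in HuT78, Jurkat and K562, those in H3K9me3 21, 545 and 415, and H3K27me3 peaks in H3K9me3 5354, 6813 and 7377. With the stricter fold these were 141, 869 and 2072, then 97, 1412 and 1086, then 4635, 5485 and 6248.

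For H3K27me3 at missing acetylation, the ratio to chance stayed above 1 in the 3 pairs with an excess. With the stricter fold in H3K27ac it was 1.17 for Jurkat peaks in HuT78 H3K27me3 and 1.94 for HuT78 peaks in K562, both above the range of chance. The other 3 pairs went from within that range to below it, at 0.847 (0.780 to 0.921) for HuT78 peaks in Jurkat, 0.782 (0.697 to 0.921) for K562 peaks in HuT78 and 0.817 (0.744 to 0.892) for K562 peaks in Jurkat. With the same number of peaks by fold HuT78 peaks in Jurkat were below it too, at 0.794 (0.689 to 0.868). The difference between missing and shared acetylation is positive by selection and carries no weight. With the stricter fold in H3K27ac it was 14.8 points for Jurkat peaks in HuT78 H3K27me3, 35.2 for HuT78 peaks in K562, 9.67 for K562 peaks in HuT78, 54.1 for Jurkat peaks in K562 and 9.34 for K562 peaks in Jurkat. With the same number of peaks by fold it was 8.14 for HuT78 peaks in Jurkat, 19 for Jurkat peaks in HuT78, 35.1 for HuT78 peaks in K562 and 11.7 for K562 peaks in HuT78. The ratio to chance of the length shared by H3K27me3 and H3K9me3 was 0.415 in Jurkat with the stricter fold, and 1.27 in HuT78 and 0.948 in K562 (0.882 to 1.05, so no longer below chance) after shifts of 0.1 to 1 Mb.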

Other observations

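The test of sequencing depth was chosen after the result was seen.

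Long stretches in which a line had no peak of any mark, while both other lines had peaks in at least 5 of the 100-kb bins, were found in HuT78 and K562. HuT78 had 37 of at least 1 Mb, 12 of them on the X chromosome, Jurkat had 0 and K562 had 4. Such counts depend on how much the lists of a line cover, and no chance value was computed. H3K9me3 covered 0.732% of the darkest Giemsa bands and 0.151% of the X chromosome in HuT78. In Jurkat it covered 8.92% and 10.6%, and in K562 5.78% and 1.47%. The longest HuT78 stretch, 22.7 Mb from 43700001 to 66400000 on chromosome 9 (9p11.2 to 9q13), crosses the centromere, and both other lines had peaks in only 10 of its 227 bins. The HuT78 stretch from 8100001 to 14300000 on chromosome 9 (9p24.1 to 9p22.3) was 6.2 Mb long, and both other lines had peaks in 52 of its 62 bins. In K562 a stretch of 5.9 Mb ran from 20700001 to 26600000 on chromosome 9 (9p21.3 to 9p21.2), with 10 of 59 bins marked in both other lines. Over 568 windows of 5 Mb, the HuT78 to Jurkat ratios of covered length correlated at -0.12 between H3K27ac and H3K27me3, at -0.12 between H3K27ac and H3K9me3 and at 0.28 between the methylated marks (Spearman). In the other pairs of lines these correlations lay between -0.05 and 0.24.

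The HuT78 H3K27ac list was less than 0.5 times as long as those of Jurkat and K562. Lower depth would enlarge the step between low fold values, the weight of 1 fragment over the background, but the HuT78 step was 0.319 against 0.329 in Jurkat and 0.331 in K562, 0.971 times the smaller of these, with a shortest peak of 146 bp in all 3 lists. This reading takes the column as pileup over background, which no header states. Regional loss of DNA was predicted to spare windows with balanced H3K27me3. In the 182 windows where HuT78 and Jurkat had H3K27me3 lengths within 1.5 times of each other, HuT78 still had 0.460 times the Jurkat peaks. The bootstrap interval over these windows was 0.430 to 0.492. The shortfall was thus not confined to windows with unequal H3K27me3. DNA amount was not measured, and equal H3K27me3 length does not show equal DNA, so regional loss stays open. Weaker enrichment in the HuT78 library and fewer acetylated sites in the cells may both account for the shorter list, and neither was tested.

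H3K27me3 and H3K9me3 shared more sequence than by chance in HuT78 and less in Jurkat, while in K562 it was less over whole chromosomes but not for shifts within 1 Mb (0.948, range 0.882 to 1.05). The short Raji lists also shared more than chance, with 0.00593 Mb, 12.9 times it (lowest 3.71). That rested on 25 of 8646 H3K27me3 peaks, and neither local shifts nor a filter for strong peaks was run for Raji. In HuT78 the ratio fell from 1.64 to 1.27 when shifts were kept within 1 Mb. Such shifts keep larger regional differences of any kind, so the fall is not particular to DNA amount, which was not measured. The ratio stayed above 1 for every shift (1.21 to 1.35), so larger regional differences alone did not account for the excess. Nor did weak peaks common to both libraries account for it alone: among peaks of at least 1 kb with a fold of at least 3 the ratio was 1.69 (1.40 to 2.07). Both marks were compared with the same HuT78 input, and this filter cannot remove peaks that arise from that input. A property of HuT78 cells and a property of these libraries cannot be told apart with 1 library per mark.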
